A study of Drosophila melanogaster with 6 samples.

How the data were processed

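Hi-C was performed on eye and antennal discs of third-instar larvae of genotype yw;+;+, per the labels' protocols, which describe 3 replicates of 125 discs per tissue, fixation with formaldehyde and a biotinylated bridge oligonucleotide at the ligation step. Reads were aligned with Bowtie2 2.3.4.2 to the dm6 genome, per the submitters' processing notes. The caller that turned contacts into TADs, its settings and the bin size are not given in the sources used here. The deposited files are lists of chromosome, start and end, 1 per library and 1 per tissue from pooled replicates, without scores, contacts or read numbers. All coordinates are multiples of 5000 bp, no TADs overlap, and the narrowest is 25 kb wide, so the bin was taken as 5 kb. Files of eye disc replicates 1, 2 and 3 and antennal disc replicates 2 and 3 were used, and that of antennal disc replicate 1 was not used here. Sequencing depth per sample is unknown, so no counting error can be given, and the precision rests on 3 and 2 libraries. A shallower library can lose or shift borders.

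TADs on arms 2L, 2R, 3L, 3R, 4 and X were kept, which was every TAD in the files. Borders were all TAD starts and ends, with an end and the next start at most 1 bin apart merged. Concordance of a pair of libraries was the percentage of their borders with a partner within 1 bin, compared with 1000 circular shifts of the borders of 1 library along each arm. Border sites were single-linkage clusters of all libraries' borders within 1 bin. Coverage was taken over arm lengths set by the last annotated gene. Libraries were grouped by tissue and compared by exact permutation over the 10 assignments of 5 libraries to groups of 3 and 2.

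Genes came from a RefSeq table of Release 6, the assembly of dm6, with 17673 genes on the 6 arms, 13911 of them protein-coding. The table has no strand, exons or sequence. Both ends of a gene therefore stood in for its transcription start, borders were only classed as inside or between genes, and a planned count of insulator motifs at borders was not made. A gene's distance was the mean of its ends' distances to the nearest border, averaged within and then over tissues. The 16 gene lists and their use were fixed before the data were examined; list medians were compared with 10000 random lists from the same arms, with Benjamini-Hochberg adjustment. *Dl* and *SA* found no match under their symbols and are not analysed here. The prefix rules for cuticle and glue genes also take in *Cpr*, a cytochrome P450 reductase gene, and *Sgsh*, a sulfamidase gene.

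Genes named in the text follow a rule set before the data were examined. It takes the gene nearest to the 10 sites per direction that lie farthest from the other tissue's borders, the 2 nearest and 2 farthest members of each list, and *ss*, *eya*, *so*, *ey*, *ato*, *Dll*, *hth*, *ct*, *Antp*, *Ubx* and *Abd-B*. The *Dfd* and *Scr* TADs, and the genes *gol*, *SP* and *Sfp70A4* beside named sites, were chosen after their values were seen.

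The computations were tested on simulated data. For tissue borders, 60 borders per tissue were planted among 1162 shared ones in 20 simulated sets, and 100% were recovered in each tissue. Planted borders were kept in every library of their tissue, so full recovery was fixed by the design. It checks the counting and not the power to find real tissue borders. With none planted, chance alone gave 35.1 eye-only and 16.3 antennal-only sites on average where each library kept 70% of borders. The simulated libraries had no borders of their own, whereas 922 of the 2345 real border sites were present in a single library. These simulated counts are therefore not a chance level for the real counts. For boundary concordance, the same planted sets reached the smallest possible p in 20 of 20 runs, and sets without planted borders in 1. The power for borders that some libraries of a tissue miss was not tested. For gene list distances over 17673 genes, 7% of 200 random lists of 30 genes had an unadjusted p under 0.05, as did 61.5% of lists with 60% of members drawn from genes nearer to borders than the median gene. For gene ends near borders over 17673 genes, random borders gave a fold of 1.02 and borders of which 1 in 3 was placed at a gene end 1.52.

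Alternatives covered the border tolerance, the border definition, narrow TADs, the arms, the similarity measure, the pooled lists, the gene set, the gene position, the matching of random lists, the replicate number as a block and leaving out each library. Those chosen after seeing the data were the stretch covered by all libraries, the set without eye disc 1 and antennal disc 3, the mean in place of the median TAD width, the nearer gene end, and lists rotated along the gene order or matched on gene length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.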

Results

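Chromosome folding was mapped by Hi-C, which joins and sequences DNA ends that lie close together in the nucleus, in the eye disc and the antennal disc of third-instar *Drosophila melanogaster* larvae. These epithelial primordia grow as 1 joined organ, were separated by hand, and give rise to the adult compound eye and antenna. The deposited values were the positions of topologically associating domains (TADs), the stretches of chromosome whose DNA contacts itself more than its surroundings. Lists for 5 libraries were compared, eye disc libraries 1, 2 and 3 and antennal disc libraries 2 and 3, each from a pool of 125 discs; antennal disc library 1 was not analysed here. The authors' lists from the pooled replicates of each tissue served as a further reference; they are labelled as taken from all replicates, so the antennal one is not limited to libraries 2 and 3. Sequencing depth was unknown, since the files held neither contacts nor scores.

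The genome was cut into a similar number of domains of similar size in both discs. The eye disc libraries held 1188, 1142 and 1116 TADs, a mean of 1149 ± 36.5 (SD, n = 3), and the antennal disc libraries held 1186 and 1217, a mean of 1202 ± 21.9 (SD, n = 2). The median TAD was 96.7 ± 5.77 kb wide in the eye disc (SD, n = 3) and 95 ± 7.07 kb in the antennal disc (SD, n = 2). TADs covered 95.5% ± 4.35 of the 6 chromosome arms in the eye disc and 95.9% ± 2.45 in the antennal disc. TADs on the X chromosome were wider than those on arms 2L, 2R, 3L and 3R by 6.5 ± 4.87 kb in median width (SD, n = 5), with a difference of 0 kb in eye disc library 1 and above 0 in the other 4. None of these measures differed between the discs by more than libraries of 1 disc did. Two-sided exact permutation tests gave p = 0.4 for the count, p = 1 for the median width, p = 1 for coverage and p = 1 for the X difference; 3 against 2 libraries allow no p below 0.2.

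Eye disc library 1 and antennal disc library 3 held no TAD on chromosome 4, the small chromosome that carries the eye master gene *ey*. Their first TADs on arm 2R started at 1585001 and 1370001, and on 3R at 3605001 and 3260001, against starts at or below 465001 on both arms in the other libraries (dm6). On 3L the last TAD of eye disc library 1 ended at 23965000, while that of antennal disc library 3 ended at 27985000. The stretch covered by all 5 libraries came to 121 Mb.

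Most domain borders of the eye disc were found in the antennal disc too, and 5 libraries were too few to tell whether the discs' borders differ by more than those of replicates. A border, the point where 1 TAD ends and the next begins, was counted as shared when the other library had a border within 1 bin of 5 kb. On average 58.4% of borders were shared between an eye and an antennal library (50.3% to 68.1% over 6 pairs), against 13.4% after borders were shifted along the arms. For each of the 10 pairs of libraries the observed share was above all 1000 shifts, one-sided permutation p = 0.000999, the smallest they can give. Libraries of the same tissue shared 60.4% (50.7% to 74.8% over 4 pairs). Eye disc libraries 2 and 3 were the closest pair at 74.8%, and antennal disc libraries 2 and 3 shared 63.6%. The authors' pooled lists of the 2 tissues shared 72.8% of their borders. The pooled eye list held partners for 88.2% and 83.7% of borders jointly with eye disc libraries 2 and 3, and for 54.2% with eye disc library 1.

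**Figure D1:**
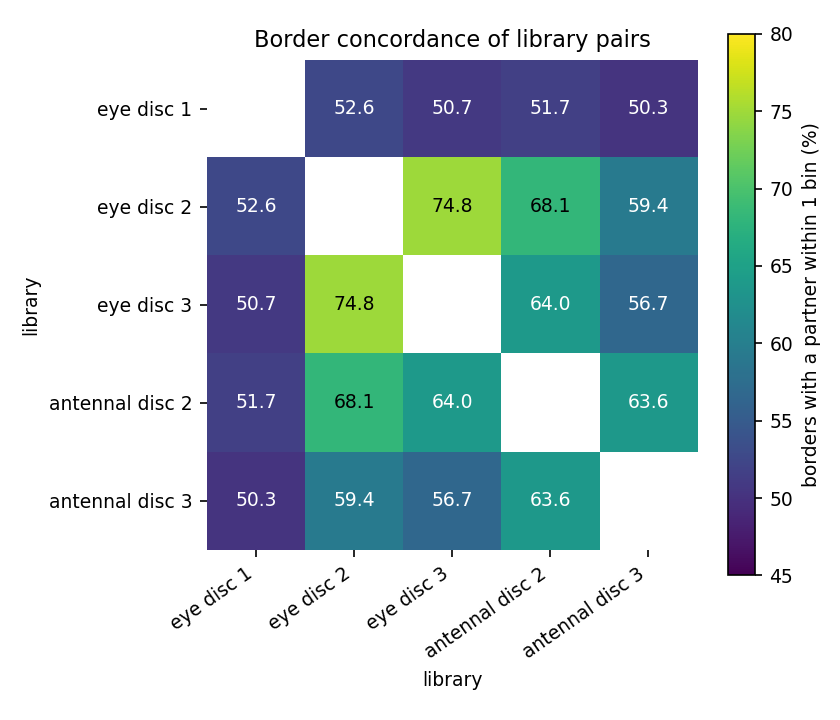
Percentage of borders with a partner within 1 bin (5 kb) for each pair of libraries, with libraries on both axes and the percentage as colour and number. Eye disc library 1 shares 50.3% to 52.6% with every other library, and eye disc libraries 2 and 3 share 74.8%.

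Same-tissue pairs exceeded pairs across tissues by 2.09 percentage points, with exact permutation p = 0.4 (one-sided; 10 splits allow no p below 0.1). The excess was −1.87 points without antennal disc library 3, and 7.20 points without eye disc library 1. Setting eye disc library 1 and antennal disc library 3 apart from the other 3 libraries gave 8.52 points, the largest value of the 10 splits. With only eye disc libraries 2 and 3 and antennal disc library 2, a choice made after seeing the data, the tissue excess was 8.79 points.

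Few borders followed the tissue when all 5 libraries had to concur, among them eye disc library 1, which shared the fewest borders with the others. Without that library, where fewer libraries must concur, 110 sites were eye-only and 124 antennal-only of 2035. Of 2345 border sites over all 5 libraries, 457 were present in each library and 922 in a single one, which can follow no split. The eye disc libraries shared 40 sites that neither antennal library had, and the antennal libraries shared 79 that no eye library had. The closest of each kind lay 10 kb from a border of the other tissue, and at a tolerance of 5 bins 21 and 31 sites remained. Some may therefore be 1 border called a few bins apart, and 1 such place can add to both counts. On 2L, for example, eye-only sites at 5795 and 12755 kb lay 10 kb from antennal-only sites at 5805 and 12765 kb. The eye-only sites farthest from any antennal border lay at *Vha68-2* and *Btk* on 2L and at *Cyp12c1* on 3L. *Vha68-2* encodes a subunit of the vacuolar proton pump, *Btk* a Tec-family tyrosine kinase and *Cyp12c1* a cytochrome P450. Their nearest antennal borders were 63.3, 60 and 60 kb away. The next 7 lay nearest to *btsz* (58.3 kb), *CG15548* (55 kb; the gene is 9.70 kb from the site), *MCU*, the mitochondrial calcium uniporter (51.7 kb), *CG13272* (45 kb), *CG34386* (45 kb), *CG42402* (35 kb; the gene is 22.9 kb from the site) and the cation-chloride cotransporter gene *Ncc69* (33.3 kb). None of these genes belongs to the lists of eye or antennal development.

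The antennal-only site farthest from any eye border, 87.5 kb away, lay on 3L at 13295001 to 13300000. It fell in the non-coding gene *lncRNA:CR45253*, within 1 bin of *SP*, which encodes the sex peptide, and of the seminal fluid gene *Sfp70A4*. The next, beside *tRNA:Ala-CGC-1-3* and *gol* on 2R (67.5 kb), was the end of the antennal libraries' last TAD on that arm, beyond the last TAD of every eye library, so it marks where calls end. The 3rd lay on X in the drosulfakinin receptor gene *CCKLR-17D1* (57.5 kb). The 4th, 52.5 kb from any eye border, lay on 3R at 6815001 to 6820000 beside *lncRNA:CR42651*, between the Hox genes *Dfd* and *Scr*. The others named were *Gfrl* (52.5 kb), *CG46525* (50 kb), *CG40228* (47.5 kb), *CG31886* (45 kb), *CR41320* (45 kb) and *CG3008* (42.5 kb). The site named for *CG40228* has no gene within 1 bin and lies 239.6 kb from that gene, the nearest by its ends. The sites of *CG40228* and *CR41320* lie on 3L beyond the last TAD of eye disc library 1, so that library could not hold them.

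**Figure D2:**
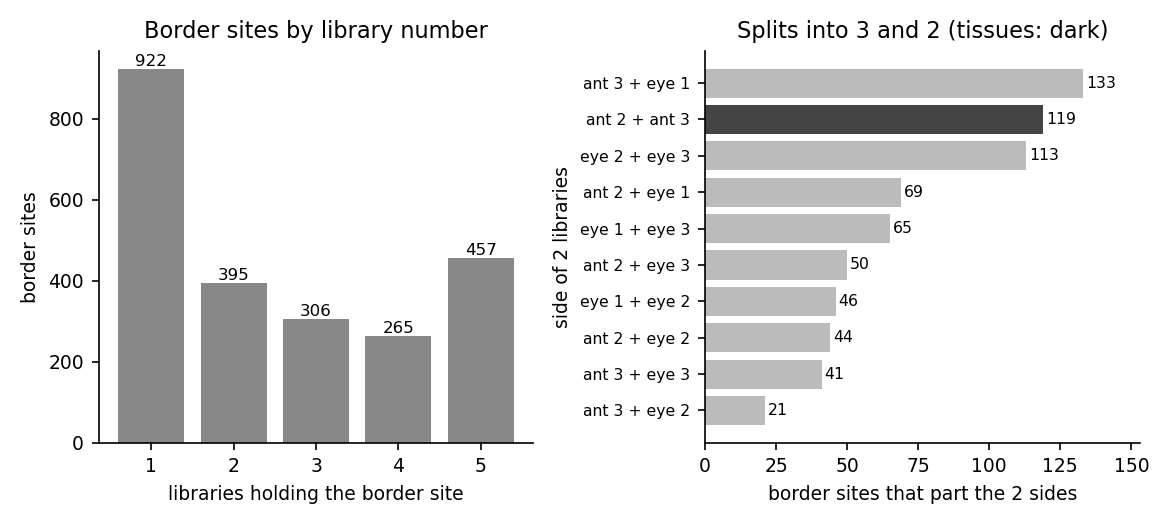
Left, number of border sites present in 1, 2, 3, 4 or 5 libraries; right, for each split of the 5 libraries into 3 and 2, the number of sites held by every library of 1 side and by none of the other, labelled by the side of 2. The split by tissue (dark) has 119 sites, and the split that sets eye disc library 1 and antennal disc library 3 apart has 133.

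No single site can pass a test with 3 against 2 libraries, so the counts were set beside those from the other splits, whose highest were 82 sites held by a side of 3 and 68 held by a side of 2; inside the stretch that all libraries cover, a choice made after seeing the data, the tissue split had 40 and 66, together 106 against 92 for the split of eye disc library 1 with antennal disc library 3, while another split had 45 on the side of 3. Another split exceeded the antennal-only count at a tolerance of 0 bins (156 against 115), 2 bins (64 against 62) and 5 bins (41 against 31). The same held without eye disc library 3 (114 against 99), antennal disc library 2 (375 against 332) or antennal disc library 3 (392 against 230). The eye-only count was exceeded at a tolerance of 0 bins (108 against 43), 2 bins (76 against 36) and 5 bins (60 against 21). It was also exceeded with TAD starts only (76 against 40), borders shared by adjoining TADs only (67 against 41) and arms 2L, 2R, 3L and 3R only (61 against 35). Leaving out eye disc library 2 (113 against 70), eye disc library 3 (114 against 66), antennal disc library 2 (157 against 96) or antennal disc library 3 (203 against 71) gave the same. Neither count was exceeded without eye disc library 1, where the tissue split had 110 and 124 and no other split more than 50 on a side.

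On average, borders lay at gene-rich places in both discs. Gene ends, either of which can be the transcription start, were 1.45 ± 0.0888 times as frequent within 1 bin of a border as near shifted borders (SD, n = 5 libraries). The fold was 1.42 ± 0.113 in the eye disc (n = 3) and 1.49 ± 0.0165 in the antennal disc (n = 2), a difference with p = 0.6 in the two-sided exact permutation test. In each library the frequency was above all 1000 shifts (one-sided permutation p = 0.000999). Borders fell between genes about as often as shifted borders did, with a mean difference of −1.39 ± 2.06 percentage points (SD, n = 5). The shortfall was largest in eye disc library 1, at −3.33 points (two-sided permutation p = 0.012), and antennal disc library 3, at −3.73 points (p = 0.002).

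Gene groups differed in how far they lay from domain borders. Genes of the ribosome lay near borders, and the medians of Polycomb-bound regulators, signalling ligands, antennal identity genes and chemoreceptor genes lay farther from borders than those of random lists. None of these calls except the ribosomal one held both against lists matched on gene density and against lists that kept neighbouring members together. The ribosomal call did not hold for the percentage of members within 1 bin of a border (14.1% against 6.52%, permutation adjusted p = 0.15). The distance of a gene was the mean over its ends and over the libraries of each tissue, and a list's median was compared with 10000 random lists from the same arms (two-sided, Benjamini-Hochberg over 16 lists fixed before the data were examined). The random lists had medians between 24.7 and 26.5 kb, and 5 lists passed at 0.05. The 92 ribosomal protein genes had a median of 15.7 kb (permutation adjusted p = 0.0032), with 67 nearer than the median gene and the list nearer in 5 of 5 libraries. *RpL34a* lay 1.16 kb from a border in the mean and *RpLP2* 2.14 kb. *RpL15* (567 kb) and *RpS3A* (111 kb) headed the other end. *RpL15* lies on 3L beyond the last TAD of eye disc library 1, and *RpS3A* lies before the first TAD of chromosome 4 in every library with calls there, so these values measure the distance to the edge of the calls.

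The 32 genes listed as Polycomb-bound regulators had a median of 45.2 kb (permutation adjusted p = 0.0064), with 25 farther than the median gene. Neither Polycomb binding nor expression was measured here. The homeobox gene *inv* lay 108 kb from borders and the Wnt gene *wg* 91.3 kb, whereas *pnr* (7.86 kb) and *eve* (10.4 kb) lay close to one. The 16 signalling genes had a median of 47.8 kb (permutation adjusted p = 0.020), with 12 farther than the median gene; *Wnt6* lay 82.1 kb away next to *wg*, while *spi* (4.71 kb) and *gbb* (11.7 kb) lay near borders. The 23 antennal identity genes had a median of 41.5 kb (permutation adjusted p = 0.031), with 15 farther than the median gene, among them *salr* (85.4 kb) and *Lim1* (75.8 kb); *amos* (9.86 kb) and *dan* (12.7 kb) were nearest. The 119 odorant and gustatory receptor genes, whose products act in smell and taste neurons, had a median of 34.3 kb (permutation adjusted p = 0.0075), with 68 farther. *Gr39b* (132 kb) and *Or65c* (106 kb) lay farthest, *Gr47b* (2.42 kb) and *Or9a* (2.86 kb) nearest. These 4 lists were farther than the median gene in 5 of 5 libraries.

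**Figure D3:**
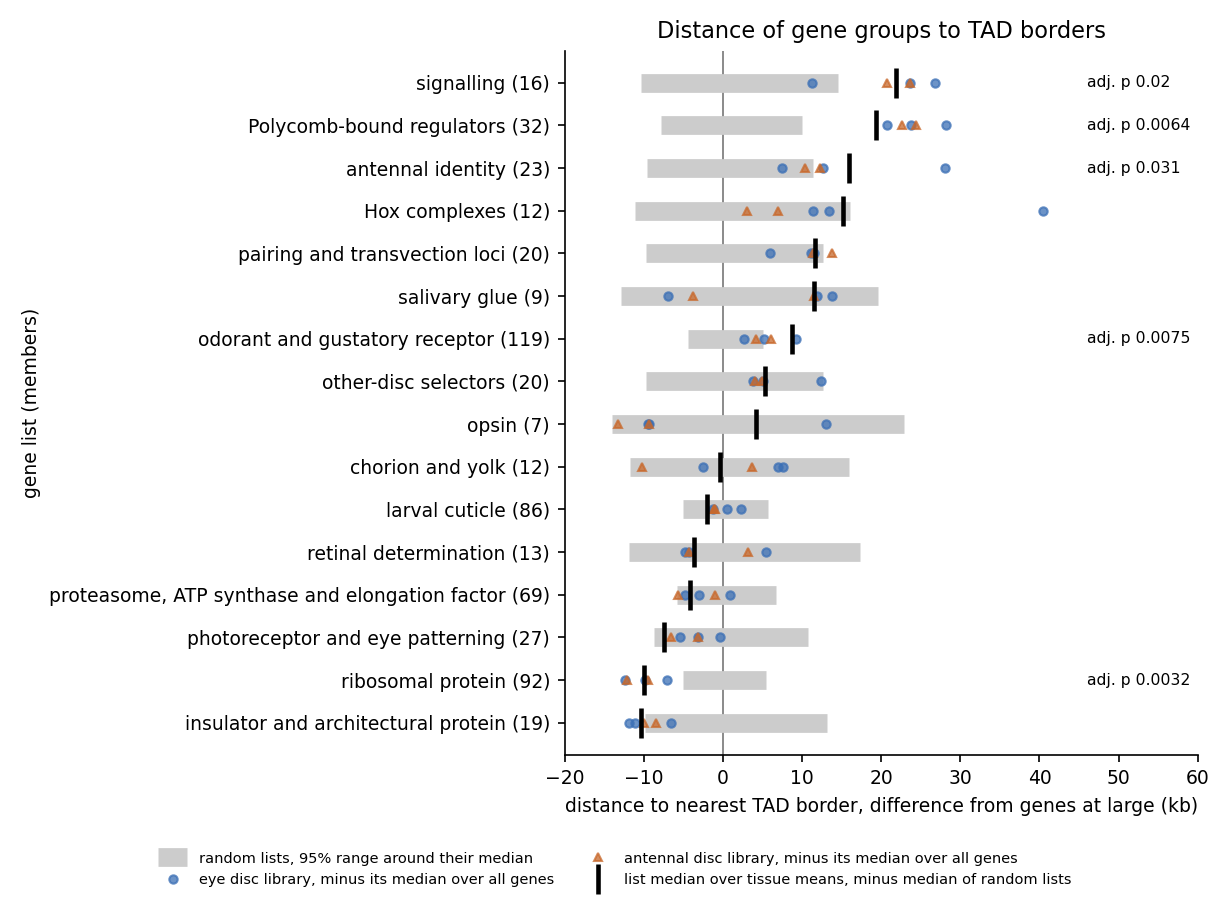
Distance of 16 gene lists to the nearest TAD border in kb, as the difference from genes at large; black ticks are list medians minus the median of random lists, grey bars the 95% range of random lists, and circles (eye disc) and triangles (antennal disc) single libraries minus their own median over all genes. The medians of ribosomal protein genes and Polycomb-bound regulators differ from those of random lists by −9.99 and 19.3 kb.

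With random lists matched on gene density the ribosomal (permutation adjusted p = 0.0096) and receptor (0.034) lists passed and the Polycomb-bound (0.144), signalling (0.166) and antennal identity (0.224) lists did not; with lists rotated along the gene order, chosen after seeing the data, the ribosomal (0.0032) and Polycomb-bound (0.019) lists passed and the receptor (0.076), antennal identity (0.103) and signalling (0.139) lists did not. The receptor list did not pass without eye disc library 1 (0.155) or antennal disc library 3 (0.166). Neither it (28.8 kb) nor the antennal identity list (33.5 kb) passed in the pooled lists (0.341 each). The antennal identity and signalling lists did not pass without antennal disc library 3 (0.081 and 0.059). Nor did they by the nearer gene end (26.1 kb, 0.75, and 39.1 kb, 0.132), also chosen after seeing the data. With only borders shared by adjoining TADs the antennal identity list did not pass (permutation adjusted p = 0.058).

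Neither list of eye genes passed the test. The 13 retinal determination genes had a median of 22.9 kb (permutation adjusted p = 0.74) and the 27 photoreceptor and eye patterning genes 18.1 kb (permutation adjusted p = 0.199), the latter nearer than the median gene in 5 of 5 libraries, with 17 of its members nearer. In the retinal list *toe* (7.59 kb) and *ey* (12.4 kb) lay nearest to borders and *tsh* (77.9 kb) and *so* (50.0 kb) farthest. Among patterning genes the homeobox gene *ro* lay 2.94 kb and *emc* 3.18 kb from a border, *salr* 85.4 kb and *B-H1* 61.4 kb. The 12 Hox complex genes had a median of 39.9 kb (permutation adjusted p = 0.133), from *abd-A* (18.7 kb) and *bcd* (29.1 kb, the mean of 138 kb in eye disc library 1 and 7.35 kb in each other library, by tissue) to *pb* (50.9 kb) and *ftz* (47.6 kb). The 20 loci used in work on pairing and transvection, the regulation of a gene by its paired homologue, had a median of 37.2 kb (permutation adjusted p = 0.133), with *Men* (7.42 kb) and *pnt* (7.79 kb) near borders and *inv* (108 kb) far; the 125 kb of *ci* is its distance to the first TAD of chromosome 4, before which it lies in every library with calls there. The 20 selector genes of other discs had a median of 30.8 kb (permutation adjusted p = 0.484), from *Doc3* (4.97 kb) and *pnr* (7.86 kb) to *bi* (71.3 kb) and *nub* (52.7 kb).

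Insulator and architectural protein genes (19) had a median of 14.8 kb (permutation adjusted p = 0.105); *mod(mdg4)* lay 6.25 kb and *Trl* 6.56 kb from a border, *vtd* 542 kb, again beyond the calls of eye disc library 1, and *Cap-H2* 44.1 kb. Proteasome, ATP synthase and elongation factor genes (69) had a median of 21.3 kb (permutation adjusted p = 0.277), from *Prosalpha3* (1.26 kb) and *Rpn13* (1.70 kb) to *Rpn8* (71.1 kb) and *Rpn5* (68.3 kb). Genes of later or other tissues did not pass either: opsins (7) at 29.4 kb (permutation adjusted p = 0.746), chorion and yolk genes (12) at 25 kb (0.95), larval cuticle genes (86) at 23.4 kb (0.56) and salivary glue genes (9) at 36.7 kb (0.312). Within them *Rh2* (4.54 kb) and *Rh4* (5.0 kb), *Cp18* (7.72 kb) and *Cp15* (8.77 kb), *Lcp65Ag3* (0.688 kb) and *Cpr65Au* (1.68 kb), and *Sgsh* (7.82 kb) and *Sgs5* (18.4 kb) lay nearest. *Rh6* (42.4 kb) and *Rh3* (40.9 kb), *Cp7Fa* (32.4 kb) and *Cp7Fb* (30.4 kb), *Cpr60D* (108 kb) and *Cpr35B* (63.9 kb), and *Sgs4* (71.4 kb) and *Sgs8* (46 kb) lay farthest.

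Hox genes were the only list to pass the test for a difference between the discs, a call that did not hold once their clustering was kept in the random lists. Their median was 49.4 kb in the eye disc and 28.3 kb in the antennal disc, and 10 of the 12 genes were nearer to a border in the antennal disc. The median difference was 14.6 kb, against 95% of random lists between −3.33 and 5.75 kb (permutation adjusted p = 0.0064, two-sided). This test redraws genes and keeps the 5 libraries fixed, so its p does not measure the spread between libraries. An exact permutation of 3 against 2 libraries allows no two-sided p below 0.2. The 12 genes sit in 2 clusters, and with lists rotated along the gene order, which keeps neighbours together and was chosen after seeing the data, the permutation adjusted p was 0.47. The gap was marked in the Antennapedia complex on 3R. In the antennal disc a border separated *Dfd* from *Scr*, Hox genes of the head and first thoracic segment. *Dfd* then lay in a TAD of 52.5 ± 3.54 kb and *Scr* in one of 97.5 ± 3.54 kb (SD, n = 2). No eye library had this border, and there both genes lay in 1 TAD of 197 ± 80.8 kb (SD, n = 3). *Scr* lay 19.1 ± 3.54 kb from a border in the antennal disc and 65.5 ± 6.86 kb in the eye disc. The border was present in the authors' pooled antennal list and absent from their pooled eye list. Both lists are labelled as taken from all replicates, so they are not data separate from these libraries.

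**Figure D4:**
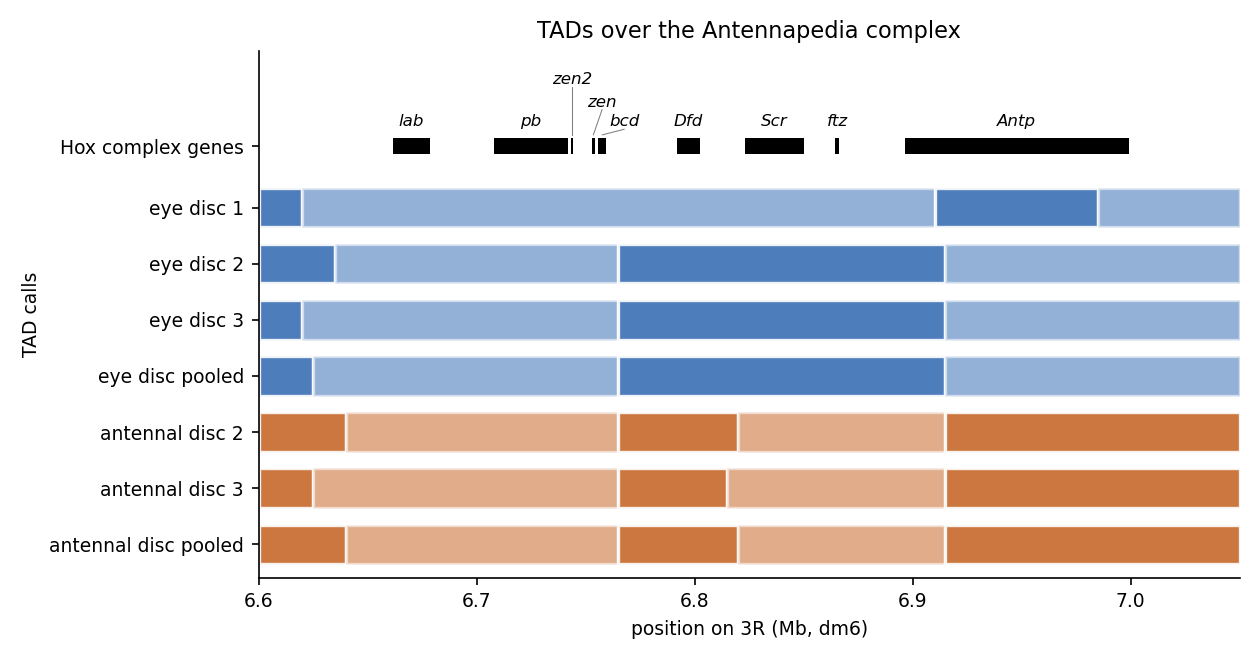
TADs over the Antennapedia complex (3R, position in Mb, dm6) in the 5 libraries and both pooled lists, as blocks in alternating shades, with the Hox complex genes in black above. The antennal lists have a border between *Dfd* and *Scr* that the eye lists lack, and eye disc library 1 has a TAD of 290 kb over most of the complex.

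The list's difference rested on eye disc library 1, whose Hox median was 61.7 kb against 35.6 and 39.5 kb in the other eye libraries. It was 1.28 kb without that library (permutation adjusted p = 1), 12.5 kb without antennal disc library 2 (permutation adjusted p = 0.106), and 0 kb in the authors' pooled lists. For the retinal determination, photoreceptor and antennal identity lists the differences were 1.34, 0 and 3.59 kb (permutation adjusted p = 1, 1 and 0.546); the other 12 lists had permutation adjusted p = 1.

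Several genes of eye and antennal fate lay in wider TADs in the eye disc on average, with wide spreads between libraries, while the TADs of *ss* and *ey* were nearly equal. Over all TADs the mean width was also larger in the eye disc, at 111 ± 8.32 kb (SD, n = 3) against 107 ± 4.67 kb (SD, n = 2). The direction is thus not particular to these genes. Widths in single libraries overlapped between the discs, as for *so* with 140, 170 and 350 kb in the eye and 165 and 160 kb in the antennal disc. *ss*, the transcription factor gene of antennal identity and of photoreceptor subtype choice (3R, 16374434 to 16403690), lay in a TAD of 83.3 ± 2.89 kb in the eye disc (SD, n = 3) and 87.5 ± 3.54 kb in the antennal disc (SD, n = 2). The retinal gene *eya* had a TAD of 71.7 ± 31.8 kb in the eye disc and 45 kb in both antennal libraries, and *so* had 220 ± 114 and 162 ± 3.54 kb. The TAD holding most of *ey* on chromosome 4 spanned 97.5 ± 3.54 kb in the 2 eye libraries with calls there and 95 kb in antennal disc library 2. The TAD of the proneural gene *ato* spanned 138 ± 118 kb in the eye disc and 110 ± 99.0 kb in the antennal disc. Among antennal genes, *Dll* had a TAD of 165 ± 40.9 kb in the eye and 105 ± 28.3 kb in the antennal disc, *hth* 222 ± 66.4 and 138 ± 124 kb, and *ct* 290 ± 147 and 195 ± 77.8 kb. The authors' pooled eye and antennal lists gave 260 and 40 kb for *hth*, 205 and 110 kb for *Dll* and 350 and 170 kb for *so*, but 90 kb in each list for *eya* and 230 and 255 kb for *ct*. A border fell inside *hth* in both antennal libraries and in eye disc library 1, inside *Antp* in all 5 libraries, inside *ey* in eye disc library 2 and antennal disc library 2, inside *eya* in eye disc library 1 and antennal disc library 3, and inside *Ubx* in eye disc library 3. *Antp* had a host TAD of 138 ± 54.8 kb in the eye and 170 kb in both antennal libraries. *Ubx* (165 ± 26.0 and 165 ± 21.2 kb) and *Abd-B* (150 ± 30.4 and 182 ± 3.54 kb) of the bithorax complex followed. No test was made for single genes.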

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

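Leaving out each library was set before the data were examined, but its use to explain this difference, and the rotation of lists, were chosen only after the result was seen. The Hox complex list lay farther from borders in the eye disc than in the antennal disc, by a median of 14.6 kb. The difference passed the permutation test against random lists, which redraws genes and does not measure the spread between libraries. A single library may account for most of it, since the difference was 1.28 kb without eye disc library 1, whose TAD of 290 kb covers most of the Antennapedia complex. Clustering of the 12 genes in 2 complexes may account for the small p as well. When the list was rotated along the gene order, which keeps neighbours together, the adjusted p was 0.47. A regulatory difference between the discs stays open for the border between *Dfd* and *Scr*, which both antennal libraries and the pooled antennal list have and every eye list lacks. The pooled lists are not data separate from the libraries, and no biological explanation was tested.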

How the results depend on the processing

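Of 472 values under alternatives 393 were classed as unchanged. For tests this meant the same direction and side of the threshold, for counts a limited fold change, and for other values a change within 1 SD. Among them were every TAD count, every between-tissue concordance (32.0% to 77.2%) and every gene-end fold (1.38 to 1.49). For library measures compared between tissues by exact permutation the side was fixed, since these splits allow no p below the threshold. Narrow TADs and extra sequences were absent, so those alternatives changed nothing; a score threshold and the motif counts could not be run. With each library left out in turn, eye minus antennal differences ranged from −2.11 to 2.13 points for coverage, −3.33 to 6.67 kb for median width and −5 to 1.25 kb for the X difference, and the within minus between concordance from −1.87 to 7.20 points; eye-only sites ranged from 66 to 110, antennal-only sites from 99 to 332, lists past the threshold from 2 to 5 and tissue-difference lists from 0 to 1. The same omissions turned the direction of chorion and yolk (18.8 to 30.9 kb), opsin (23.2 to 32.2 kb) and retinal determination genes (20.4 to 25.4 kb). Libraries of equal number shared 62.4% of borders and those of unequal number 61.7%. With 2 pairs of each kind this cannot tell whether replicate numbers pair the samples. The replicate block gave 2.13 points for coverage and 1.25 kb for the X difference, both turned. With 2 blocks no tissue difference could pass the threshold, so the block could not move those calls. A tolerance of 5 bins left 21 eye-only and 31 antennal-only sites, because nearby borders merge, and support by the pooled lists left 24 eye-only sites. The number of lists past the threshold was 3 with the pooled lists, 2 with density-matched lists and 0 for the percentage of members within 1 bin. The tissue-difference count was 0 with the pooled lists. Of alternatives chosen after seeing the data, the common stretch gave 0.271 points for coverage; the nearer gene end left 3 lists and rotation 2, with 0 tissue differences under rotation. Without eye disc 1 and antennal disc 3 there were 176 eye-only and 311 antennal-only sites, as fewer libraries must concur, 2 lists and 0 tissue differences. Lists below the threshold that turned direction were chorion and yolk at 25 kb (protein-coding genes), 29.3 kb (pooled), 25 kb (density), 0% (within 1 bin), 24.3 kb (nearer end) and 35 kb (without both libraries), opsin at 19.3 kb (pooled) and 28.6% (within 1 bin), larval cuticle at 23.4 kb (density), retinal determination and insulator genes at 0% (within 1 bin), and other-disc selectors at 16.2 kb (nearer end). Unless stated, the cause was not tested. Depth is unknown and limits which borders a library can show.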

Other observations

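The test of a border set shared by eye disc 1 and antennal disc 3 and the 4 tests on single gene lists were chosen only after the result was seen, and rotation of lists was chosen after seeing the data. Borders found in more libraries lay at denser genes. Inside the stretch that all libraries cover, the 453 sites present in all 5 libraries had 5.10 ± 4.90 gene ends within 1 bin (SD over sites), and the 783 sites present in 1 library had 2.74 ± 3.29. The difference of 2.36 gene ends was above all 10000 permutations of the sites (one-sided p = 0.0001, the smallest they can give); sites of 2, 3 and 4 libraries had 3.32, 3.94 and 4.2. Gene-dense borders may thus be the ones most readily found in either disc, a hypothesis from these calls. Shifted borders of the single libraries, over whole arms, had means of 2.64 to 2.65 gene ends in a window of the same size. Sites of 1 library were thus about as gene-dense as shifted positions, and the values cannot tell whether they are borders that are harder to find.

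Wide TADs held fewer genes per 100 kb. The correlation of width with gene content across TADs was weak, with Spearman's rho between −0.123 and −0.0632 over the 5 libraries, though TADs are not independent replicates. Shifted TADs gave a mean rho of 0.0564, and each library lay below all 1000 shifts (one-sided permutation p = 0.000999, the smallest they can give). TADs narrower than 50 kb held a median of 13.5 ± 0.755 genes per 100 kb and those of 200 kb or more 11.1 ± 0.331 (SD, n = 5 libraries). In contrast, arrays of related genes were not seen to be kept whole beyond chance. Of 102 pairs of neighbouring receptor, cuticle, chorion or glue genes at most 50 kb apart, a border parted 3.14%, against 4.67% with shifted borders (one-sided permutation p = 0.134), and the receptor pairs alone gave 3.41% against 6.99% (p = 0.102).

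The split by tissue had 119 sites held by every library of 1 side and none of the other, and 2 of the 10 splits reached that number; the highest other split had 133. With 10 splits no share under 0.05 can be had. That highest split set eye disc 1 and antennal disc 3 apart, and inside the stretch that all libraries cover it had 92 sites against 106 for the split by tissue, then the highest of the 10.

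Eye disc 1 and antennal disc 3 had the lowest coverage and the lowest mean border concordance with the other libraries, at 51.3% and 57.5%. They differed in degree: eye disc 1 shared at most 52.6% with any library, antennal disc 3 63.6% with antennal disc 2. Regions outside the stretch that all libraries cover account for their lead in sites held by split but not for the concordance. Inside that stretch, setting the 2 apart still exceeded the tissue grouping, by 7.29 against 2.08 percentage points, and did so on 5 of 5 arms. The widest TAD spanned 2365 kb in eye disc 1 and 940 kb in antennal disc 3, against 445 to 500 kb in the other libraries. Such blocks count as covered, so sparse calls inside the stretch are not excluded. For eye disc 1, borders displaced by a few bins do not account for the low concordance either, because at a tolerance of 5 bins the excess of eye disc 1 with eye disc 2 over shifted borders was only 71.1% ± 8.48 (SD over arms) of that of eye disc 3 with eye disc 2; displacement was not tested for antennal disc 3 and stays open there. Whether the pair has a border set of its own cannot be told apart from scatter, with a difference of −1.36 points over all arms and a mean of −2.74 ± 3.90 (SD over 5 arms), and lower depth stays a possible explanation that the files cannot test.

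The distances of gene lists may partly reflect gene density, since 2 of the 5 lists passed against density-matched lists. Their small p-values may partly reflect clustering, since 2 passed after rotation. Density matched in 5 classes of the gene number within 50 kb did not account for the ribosomal protein genes. They lay at 15.7 kb against 24.0 kb (95% of lists 19.6 to 29.2 kb) in density-matched lists, permutation adjusted p = 0.0096. Density within these classes or at a finer scale was not matched and stays open. For the Polycomb-bound list at 45.2 kb, density may account for part of the distance. The random median rose from 25.9 kb (18.1 to 35.9 kb) to 32.1 kb (22.1 to 43.3 kb) with matching, which ended the call at permutation adjusted p = 0.144, whereas rotation left it at 0.019. For the receptor genes rotation widened the random range from 21.1–30.6 kb to 19.8–32.4 kb and ended the call at 0.076. The random median was 25.6 kb under rotation, and the list at 34.3 kb stayed above the range. Clusters of receptors may thus account for part of the small p, while the distance itself did not shrink.

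The pooled antennal list had 138 of 1238 borders with no partner in antennal disc libraries 2 and 3, and 89 of these had one in an eye library; that list is labelled as taken from all replicates, and replicate 1 was not analysed here, so borders of replicate 1 are not excluded among the 138. The pooled eye list had 22 of 1146 without a partner in any eye library.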
